A study of Homo sapiens with 48 samples.

How the data were processed

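The study used HEK293-derived human cells in which the endogenous DHX15 or DHX38 gene carries a degron tag, so that the small molecule dTAG13 is meant to remove the tagged protein. The loss of the protein was not measured here. Cells of each line received 100 nM dTAG13 or the solvent DMSO for 2 h, and total RNA and chromatin-associated RNA were taken from the same plates, with poly(A) RNA removed from the chromatin RNA only, per the labels' protocols. The labels list 48 libraries in 8 groups of 6 libraries. Each of the 4 comparisons set dTAG13 against DMSO within 1 line and 1 fraction. Alignment and quantification used STAR 2.7.3a, RSEM 1.3.3, DESeq2 1.26.0 and bedtools on GRCh38, per the submitters' processing notes, which do not say which tool made the intron tables.

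The 8 deposited tables give introns whose splicing index rose or fell, with 1 value per treatment. The authors' counts of spliced reads and of unspliced boundary reads are whole numbers without normalization, and they carry no library of their own, so the 6 libraries of a group are pooled in them. The deposited splicing index is a fraction from 0 to 1. It equalled 2 times the spliced count over the sum of 2 times the spliced count and the unspliced count in every table, and an index near 1 means that nearly all reads at the intron were spliced. The deposited delta score is the dTAG13 index minus the DMSO index. The deposited p-value equalled a two-sided Fisher's exact test on the 4 counts, within a relative difference of 1e-06, for 100% of introns, and the deposited adjusted p-value follows Benjamini-Hochberg. From the ratios of adjusted to raw p-values, the authors had tested 55577 introns in dDHX15 chromatin RNA, 79102 in dDHX15 total RNA, 62149 in dDHX38 chromatin RNA and 81505 in dDHX38 total RNA. Every listed intron had at least 10 reads in each of the 4 counts, an adjusted p-value under 0.05 and an index change over 0.05, and 100% of the listed introns were annotated. Introns that did not pass those conditions are not analysed here.

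The counting tests compare pooled reads, so the spread between libraries does not enter them. The p-values and intervals cover counting error only and would be too small if libraries of 1 group differ. Library totals are not used here. The median intron had 524, 599, 571 and 672 reads over its 4 counts in dDHX15 chromatin, dDHX15 total, dDHX38 chromatin and dDHX38 total RNA.

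Lines of 1 intron that differed only in the overlapping gene were merged into 1 intron with 1 host gene, chosen among genes that contain the intron with protein-coding genes preferred. Where no gene contained the intron, an overlapping gene was taken, which applied to 3, 9, 1 and 5 introns in dDHX15 chromatin, dDHX15 total, dDHX38 chromatin and dDHX38 total RNA. Gene IDs were matched to symbols for 6539 of 6553 IDs. An intron inside more than 1 protein-coding gene is uncertain in its gene, as are introns of pseudogenes and of gene families with near-identical copies, ribosomal protein genes among them. Coordinates are those of the deposited tables on GRCh38, and intron length is end minus start. The log2 change is that of the ratio of spliced to unspliced reads, dTAG13 over DMSO, with the standard error of a log ratio of 4 counts. Shares carry exact Clopper-Pearson 95% intervals, and the intervals of an index carry the exact interval of the spliced share over to the index. Shares over introns describe the lists, since introns of 1 gene are not independent.

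Comparisons, tests, gene lists and the rule for named genes were set in advance. The plan for counts per library was edgeR's quasi-likelihood test, and for tables of introns already selected by the authors it was to take membership from the deposited tables. The tables were of the second kind, so no new test decided membership. The named introns were, in each comparison, the 10 with the highest and the 10 with the lowest log2 change among introns with a mean of at least 20 reads per library, at most 1 per gene; up to 4 introns per gene list with the largest absolute log2 change; every listed intron of DHX15, DHX38 and SUGP1; and, between the lines, the 10 introns that moved in opposite directions with the largest sum of absolute changes. A mean of 20 reads was read as 240 reads over the 4 counts, on the assumption that the counts are sums over 12 libraries. Any other gene is said to be chosen after its values were seen. Some introns that the rule names are not reported here.

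Overlaps matched chromosome, start, end and strand, with a two-sided Fisher's exact test of direction by direction. These tests count introns of 1 gene as independent, so their p-values would be too small where such introns move together. The overlap of independent lists is the product of the list sizes over the larger number of introns tested. Intron length was compared between risen and fallen introns by a two-sided permutation test of the difference of medians with 100000 resamples, and the share of introns without GT-AG ends by Fisher's exact test, with Benjamini-Hochberg adjustment over the 4 comparisons. The 15 gene lists held G-patch proteins with the targets, spliceosomal helicases, U2 snRNP proteins, catalytic factors and those of the second step, SR proteins and their kinases, hnRNP proteins, cytoplasmic ribosomal proteins, snoRNA host genes, immediate early genes, heat shock and unfolded protein response genes, p53 targets, mitotic and cohesion genes, nonsense-mediated decay factors, elongation and termination factors, and markers of other cell types. Genes with a risen (or fallen) intron were set against the other genes with a listed intron by two-sided Fisher's exact tests, 110 in all, with Benjamini-Hochberg adjustment over them. The background therefore holds only genes with a listed intron, and counts adjusted over the list alone could not be computed because p-values of introns that were not listed are not used here. Each list's median log2 change was placed among 10000 random lists of the same size with similar reads. Odds ratios were Mantel-Haenszel estimates with intervals from 1000 bootstrap resamples of genes. Intervals of a ratio between odds ratios came from the counts of introns instead, and these treat introns of 1 gene as independent. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

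The procedure was tested on simulated counts for all listed introns of each comparison, with known changes in few of them. The number of tests was recovered exactly. In dDHX15 chromatin RNA 74, 69 and 57 of 9654 introns were changed by 0.5, 1 and 2 on the log2 scale. With so few changed, the adjusted p is harder to pass than in the deposited tables, and spread between libraries was not simulated. The shares called hold for that setting only. In dDHX15 chromatin RNA 6.76% of introns changed by 0.5 on the log2 scale were called, 53.6% of those changed by 1 and 98.2% of those changed by 2. In dDHX15 total RNA the shares were 7.35%, 44.4% and 78.3%, in dDHX38 chromatin RNA 10.5%, 38.9% and 91.0%, and in dDHX38 total RNA 7.35%, 47.4% and 87.5%. A first bar of 90% at a change of 2 was not met in total RNA and was replaced by a calculation of expected power, which the numbers past the adjusted p-value met in all comparisons. Alternatives were a stricter adjusted p-value of 0.01, a minimum mean of 20 reads, a minimum log2 change of 1, a minimum index change of 0.1, counting genes, 1 intron per gene, and a match of at least 1 splice site. Splice site scores, exon skipping and distances to other sites need a genome or annotation and are not analysed here.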

Results

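The data described the splicing of annotated introns in cells where either of a pair of DEAH-box RNA helicases was targeted for degradation. DHX15, the human counterpart of yeast Prp43, takes part in releasing and recycling spliceosomes, and DHX38, the counterpart of Prp16, acts between the catalytic steps. HEK293-derived cells whose DHX15 or DHX38 carried a degron tag received 100 nM dTAG13, a compound that directs tagged proteins to degradation, for 2 h. DMSO was the control. Total RNA and poly(A)-depleted chromatin-associated RNA, which is rich in nascent transcripts, were measured in 6 libraries per group. The measure was the splicing index, in which spliced reads are set against unspliced reads at an intron, with 1 pooled value per treatment, so no spread between replicates could be given. The listed introns numbered 9654 in dDHX15 chromatin RNA, 6615 in dDHX15 total RNA, 14745 in dDHX38 chromatin RNA and 9994 in dDHX38 total RNA, which were 17.4%, 8.36%, 23.7% and 12.3% of the introns tested. Of introns past the adjusted p, 583 of 10237, 6486 of 13101, 956 of 15701 and 9220 of 19214 were not listed, so the lower shares in total RNA also reflect the other listing conditions. The middle 90% of these introns had 167 to 1596 reads, 188 to 2081 reads, 182 to 1719 reads and 203 to 2386 reads, in the same order, and the median standard error of a log2 change was 0.28, 0.31, 0.27 and 0.28.

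**Figure D1:**
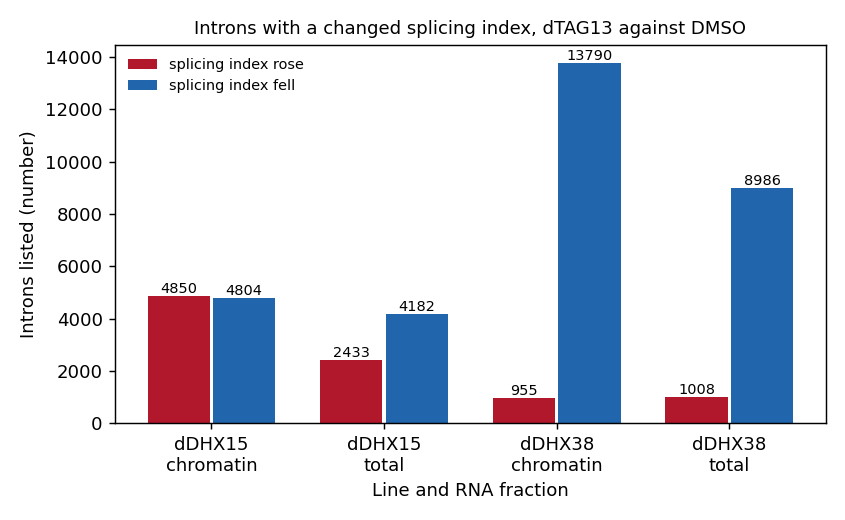
Number of listed introns (vertical axis) whose splicing index rose (red) or fell (blue) after dTAG13, by line and RNA fraction (horizontal axis). In dDHX38 chromatin RNA 955 introns rose and 13790 fell, while in dDHX15 chromatin RNA 4850 rose and 4804 fell.

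In dDHX15 cells dTAG13 changed chromatin RNA in both directions. An intron of SRSF5, an SR protein that regulates splicing (ENSG00000100650.15, chromosome 14, 69769252 to 69769510), rose from an index of 0.0764 (95% interval 0.0392 to 0.131) to 0.515 (0.475 to 0.554), a log2 change of 3.68 with a standard error of 0.46. An intron of RBM5, a G-patch protein that regulates splicing (ENSG00000003756.16, chromosome 3, 50100052 to 50100531), rose from 0.180 to 0.705, a log2 change of 3.45 ± 0.21 (SE), with an adjusted p of 1.95e-71 in the authors' deposited table. The other introns among the 10 highest lay in CCDC14, SPTAN1, NKTR, INTS3, SREK1, PPP6R1, RBM28 and OS9. Among the 10 lowest, an intron of LONP1, a mitochondrial protease (ENSG00000196365.11, chromosome 19, 5699206 to 5700788), fell from 0.764 to 0.293, a log2 change of -2.97 ± 0.19 (SE), and others lay in HERC2P2, SCAF8, PRPF39, AARS, TRMT11, CPNE1, CDC42BPB and NARS2. HERC2P2 is a pseudogene with near-identical relatives, so its value is uncertain. In all, 4850 introns rose, with a median index of 0.601 before and 0.772 after, and 4804 fell, with a median of 0.816 before and 0.659 after. The share that rose was 50.2% (exact Clopper-Pearson 95% interval 49.2 to 51.2).

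Cytoplasmic ribosomal protein genes rose together in dDHX15 chromatin RNA. All 72 genes of the list with a listed intron had a risen intron and 3 of 72 had a fallen one, and over introns 202 rose and 3 fell. Among the other genes 68.2% had a risen and 67.1% a fallen intron (Fisher's exact test, p = 2e-12 and 3.9e-29, Benjamini-Hochberg adjusted p = 1.1e-10 and 4.3e-27). RPL34 changed by 1.86 ± 0.22 (SE, log2), RPL10 by 1.81 ± 0.12 and RPS12 by 1.80 ± 0.25. These genes have processed pseudogenes elsewhere in the genome, which can take part of their spliced reads. Genes that host snoRNAs, the guide RNAs of ribosomal RNA modification, had a risen intron in 19 of 19 genes (Fisher's exact test, p = 0.0017, adjusted p = 0.022), with 58 introns risen and 14 fallen, EEF1A1 among them at 1.48 ± 0.09 (SE, log2). The hnRNP genes also had a risen intron in 19 of 19 genes (Fisher's exact test, p = 0.0017, adjusted p = 0.022), but with 58 introns risen and 33 fallen, and HNRNPH1 rose by 2.43 ± 0.08 while HNRNPA3 fell by 2.18 ± 0.43 on the log2 scale. Of 8 heat shock and unfolded protein response genes, 1 had a fallen intron (Fisher's exact test, p = 0.0031, adjusted p = 0.031), and the list had 35 risen and 2 fallen introns, HSPH1 at 1.78 ± 0.34 (SE, log2) among them. With introns past an adjusted p of 0.01, the adjusted p was 0.065 for the hnRNP genes and 0.12 for the heat shock genes. The hnRNP genes had 4.79 listed introns per gene against 3.03 in other genes, and a gene with more introns can have a risen intron more often. In the authors' length classes, 55.9% of short introns (up to 375 bases) and 56.6% of medium ones (up to 3281 bases) rose here. Long and extra long introns rose less often, at 34.3% and 17.5%. Median lengths were 333 bases for snoRNA host genes, 405 bases for heat shock genes and 562 bases for hnRNP genes, against 970 to 973 bases in other genes. Within deciles of intron length, a test added after the list results were seen, the odds ratio of rising against other introns was 3.11 (95% interval 1.44 to 9.97), 11.8 (2.14 to 22.1) and 1.56 (0.894 to 3.09), in the same order, and the interval for hnRNP genes includes 1.

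In dDHX15 total RNA an intron of DDX5, a DEAD-box RNA helicase (chromosome 17, 64500774 to 64501056), rose from 0.0283 to 0.461, a log2 change of 4.87 ± 0.46 (SE), and the SRSF5 intron named above rose from 0.0739 to 0.633, a log2 change of 4.43 ± 0.20. The RBM5 intron rose from 0.473 to 0.933, a log2 change of 3.95 ± 0.17 (SE). SRSF2, PNISR, RBM25, CLK4, SFPQ and RBM39 held others of the 10 highest, and 1 more only overlapped the gene TRIM27 and lay mostly outside it. At the low end an intron of TICRR, a regulator of DNA replication initiation (chromosome 15, 89616496 to 89618151), fell by 3.29 ± 0.26 on the log2 scale, from 0.892 to 0.459, and an intron of PCF11, a transcription termination factor, fell by 2.87 ± 0.23. CEP350, SCAF8, TRAF2, ASH1L, DDI2, RSRP1, KDM2B and CHD9 held the others of the 10 lowest. Over all introns 2433 rose, with a median index of 0.757 before and 0.877 after, and 4182 fell, with a median of 0.917 before and 0.815 after, so 36.8% rose (95% interval 35.6 to 38.0).

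No gene list passed the adjusted threshold in dDHX15 total RNA. SR proteins and their kinases had a risen intron in 12 of 16 genes, against 46.8% of other genes. A fallen one was found in 7 of 16, against 70.1% (Fisher's exact test, p = 0.041 and 0.029, adjusted p = 0.24 and 0.19). Over introns 19 rose and 17 fell, SRSF2 at 3.34 ± 0.25 and SRSF6 at 2.57 ± 0.22 (SE, log2) among the risen. The list's median log2 change of 1.16 stood at percentile 99.9 of random lists. Other lists also stood near the ends, as ribosomal protein genes at percentile 99.4 and elongation and termination factors at 0.58 in dDHX38 total RNA. Elongation and termination factors had a fallen intron in 17 of 18 genes (Fisher's exact test, p = 0.02, adjusted p = 0.15). Ribosomal protein genes had 7 risen and 7 fallen introns in 13 genes (adjusted p = 1 for risen and 0.66 for fallen). Of the immediate early genes, 3 of 3 had a fallen intron (adjusted p = 0.93), MYC at -1.98 ± 0.16 (SE, log2) and KLF6 at -1.65 ± 0.31 among them.

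In dDHX38 cells the index of most listed introns fell in chromatin RNA after dTAG13. An intron of BRWD1, a bromodomain protein (chromosome 21, 39312901 to 39313071), fell from an index of 0.861 to 0.446, a log2 change of -2.94 ± 0.21 (SE), with an adjusted p of 1.14e-47 in the authors' deposited table. An intron of MDN1, an ATPase of ribosome assembly (chromosome 6, 89749370 to 89749542), fell from 0.969 to 0.789, a log2 change of -3.07 ± 0.46 (SE). An intron of CHAF1A, a chromatin assembly factor, fell by 2.84 ± 0.27, and an intron of MAVS, an adaptor of antiviral signalling, fell by 2.71 ± 0.36. RBM19, USP15, ZC3H4, CTTN, ADRBK1 and UHMK1 held the other introns of the 10 lowest. The 10 highest changes were smaller, from 1.67 ± 0.43 in CTD-2611K5.5 to 1.93 ± 0.39 (SE, log2) in CLK4, a kinase of SR proteins, with EME2, PIM3, SPTAN1, RACGAP1, DYNC1LI1, HADH, SRRM2 and FTSJ3 between them. In all, 955 introns rose and 13790 fell, so 6.48% rose (95% interval 6.08 to 6.89), and the median index of the fallen introns went from 0.787 to 0.624.

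**Figure D2:**
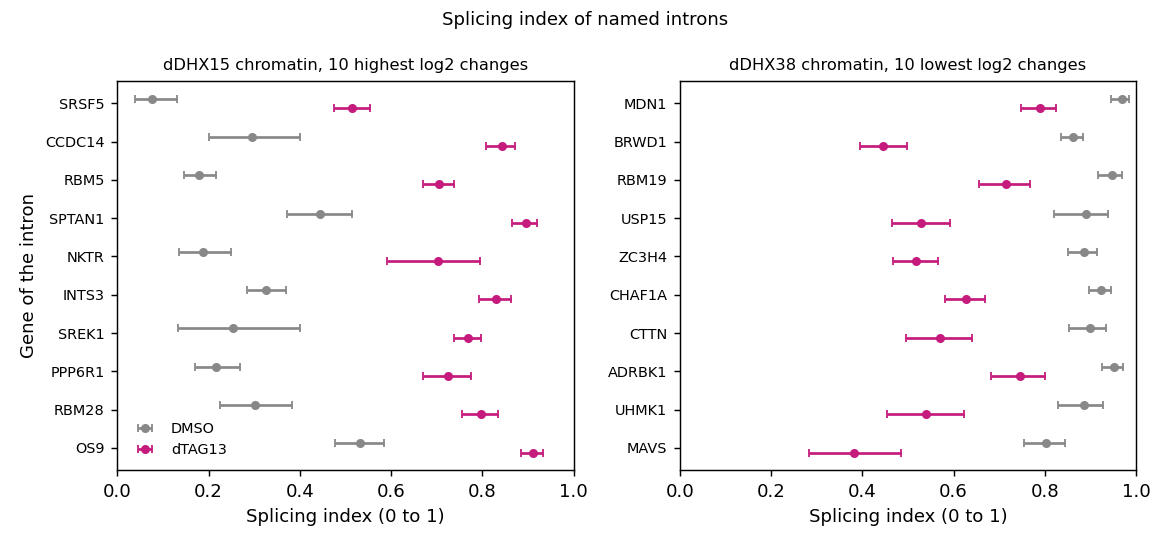
Splicing index from 0 to 1 (horizontal axis) of the introns with the 10 highest log2 changes in dDHX15 chromatin RNA (left) and the 10 lowest in dDHX38 chromatin RNA (right), by gene (vertical axis). Points are pooled values for DMSO (grey) and dTAG13 (magenta), bars are 95% intervals of counting error, and the SRSF5 intron moved from 0.0764 to 0.515 while the BRWD1 intron moved from 0.861 to 0.446.

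Against this general fall, several gene lists had more risen introns in dDHX38 chromatin RNA. Ribosomal protein genes had a risen intron in 28 of 64 genes, against 18.9% of other genes, and a fallen one in 49 of 64, against 94.6% (Fisher's exact test, p = 6.8e-06 and 1.7e-06, adjusted p = 0.00019 and 6.4e-05), although 91 of their introns fell and 38 rose. RPL22 at -2.22 ± 0.55 and RPS24 at -1.47 ± 0.11 (SE, log2) were among the fallen. Host genes of snoRNAs had a risen intron in 12 of 19 genes, against 19.1% of other genes. Fewer of them than of other genes had a fallen one, 14 of 19 against 94.4% (Fisher's exact test, adjusted p = 0.00073 and 0.032). SNHG15 at 1.34 ± 0.15 and NOP56 at -1.64 ± 0.15 (SE, log2) were among these genes. Heat shock and unfolded protein response genes had a risen intron in 6 of 7 genes (Fisher's exact test, p = 0.0003, adjusted p = 0.0055), with 13 introns risen and 11 fallen, HSP90AA1 at 1.22 ± 0.20 and DNAJA1 at 1.15 ± 0.25 (SE, log2) among the risen. A risen intron was found in 10 of 21 hnRNP genes (adjusted p = 0.031), and all 21 also had a fallen one, as in HNRNPU at -1.75 ± 0.09 (SE, log2). The hnRNP genes had 5.76 listed introns per gene against 3.79 in other genes, and the odds ratio of rising over introns, 1.75 (0.860 to 3.09), has an interval that includes 1. SR proteins and their kinases had a risen intron in 8 of 17 genes (adjusted p = 0.074), and this adjusted p was 0.043 with a mean of at least 20 reads. Elongation and termination factors had a risen intron in 11 of 23 genes (adjusted p = 0.022), and this adjusted p was 0.39 with introns past an adjusted p of 0.01.

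In dDHX38 total RNA an intron of RREB1, a zinc finger transcription factor (chromosome 6, 7231908 to 7246423), fell from 0.915 to 0.505, a log2 change of -3.40 ± 0.50 (SE). An intron of CDK9, the kinase of the elongation factor P-TEFb (chromosome 9, 127786241 to 127786700), fell from 0.891 to 0.552, a log2 change of -2.72 ± 0.20. RASSF1, KNTC1, ZNF638, VPS13A, TNRC6A, NDE1 and NCAPH2 held other introns of the 10 lowest. EPS15L1 at 2.65 ± 0.53 (SE, log2) was the highest, followed by ABHD14B, GPM6B, ECH1, VPS39, UBXN6, FGFR1, ADAM15, NCKAP1 and the spliceosomal helicase gene DHX8 at 1.97 ± 0.52, and the ABHD14B intron lies within more than 1 protein-coding gene. In all, 1008 introns rose and 8986 fell, so 10.1% rose (95% interval 9.50 to 10.7), and the median index of the fallen introns went from 0.907 to 0.807. No gene list passed the adjusted threshold. Elongation and termination factors had a risen intron in 0 of 20 genes (Fisher's exact test, p = 0.021, adjusted p = 0.15) and a fallen one in 20 of 20 (p = 0.16, adjusted p = 0.58), and ribosomal protein genes had 3 risen and 27 fallen introns (adjusted p = 0.86 and 1).

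The remaining lists did not pass the adjusted threshold in any comparison, and their counts in dDHX15 chromatin RNA were as follows. The U2 snRNP genes had a risen intron in 14 of 15 genes and a fallen one in 12 of 15 (Fisher's exact test, p = 0.048 and 0.29, adjusted p = 0.26 and 0.7). They had 34 risen and 43 fallen introns, and 5.13 listed introns per gene against 3.03 in other genes. Introns of U2SURP (2.88 ± 0.31) and SF3B1 (2.23 ± 0.28) rose. Introns of SUGP1 (-2.71 ± 0.63) and SF3B3 (-2.22 ± 0.33, SE, log2) fell. Spliceosomal helicases had a risen intron in 11 of 12 genes and a fallen one in 11 of 12 (adjusted p = 0.51 and 0.34). Over introns 25 rose and 34 fell, DDX17 at 2.66 ± 0.33 and DDX41 at -1.76 ± 0.23 (SE, log2) among them. G-patch proteins had a risen intron in 9 and a fallen one in 13 of 15 genes (adjusted p = 0.93 and 0.46), with 18 introns risen and 38 fallen. Catalytic factors and those of the second step had a risen intron in 6 and a fallen one in 9 of 11 genes (adjusted p = 0.73 and 0.74), although 27 of their introns rose and 14 fell. Of 4 p53 targets, 1 had a risen and 3 had a fallen intron (adjusted p = 0.44 and 1), XPC at -1.59 ± 0.32 (SE, log2) among them. Mitotic and cohesion genes had a risen intron in 10 and a fallen one in 12 of 15 genes (adjusted p = 1 and 0.7), with 23 introns risen and 23 fallen. Nonsense-mediated decay factors had a risen intron in 9 and a fallen one in 9 of 12 genes (adjusted p = 1 for both). Over introns 19 rose and 27 fell, UPF1 at 2.42 ± 0.27 and SMG5 at -1.87 ± 0.20 (SE, log2) among them. Of 16 markers of blood, liver, fibroblast and muscle cells, 0 had a listed intron in any comparison.

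The targeted genes were read at the RNA level only, which does not check the loss of the proteins. The DHX15 gene had 1 risen and 3 fallen introns in dDHX15 chromatin RNA, the largest change being -1.56 ± 0.28 (SE, log2), and 1 risen intron at 1.20 ± 0.17 and 0 fallen in dDHX15 total RNA. DHX38 had 0 risen and 12 fallen introns in dDHX38 chromatin RNA, the largest change being -1.96 ± 0.24 (SE, log2), and 2 risen and 5 fallen introns in dDHX38 total RNA. SUGP1, a G-patch protein that works with DHX15, had 1 risen intron at 2.14 ± 0.36 and 1 fallen at -2.71 ± 0.63 (SE, log2) in dDHX15 chromatin RNA. In dDHX15 total RNA it had 3 risen and 1 fallen introns, and its intron at 19303449 to 19303723 on chromosome 19 rose by 2.62 ± 0.34 (SE, log2). In dDHX38 total RNA the same SUGP1 intron fell by 0.89 ± 0.19, and 0 introns of the gene rose while 5 fell, against 0 and 2 in dDHX38 chromatin RNA.

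Where an intron was listed in both fractions, its direction was mostly the same. For dDHX38 this came mostly from the general fall. The fractions came from the same plates, so a difference between the plates of each treatment would enter both, and the fractions are not independent. For dDHX15, 1313 introns were shared, of which 517 rose in both and 760 fell in both, so 97.3% had the same direction (95% interval 96.2 to 98.1; Fisher's exact test, p = 2.7e-316), against 51.7% from the shares of risen introns in each fraction alone. The SRSF5, RBM5 and SCAF8 introns named above were among them. For dDHX38, 3014 introns were shared, of which 36 rose in both and 2919 fell in both, so 98.0% had the same direction (97.48 to 98.51; Fisher's exact test, p = 2.2e-47), against 95.7% from those shares alone. Of the 62 shared introns that rose in dDHX38 chromatin RNA, 26 fell in total RNA, which was 41.9% (29.5 to 55.2). Another 33 introns fell in chromatin and rose in total RNA. Independent lists would share at most 807 and 1808 introns, although introns with many reads can be listed in both fractions for that reason alone. The median difference of absolute log2 changes, chromatin minus total, was -0.0031 (95% interval -0.034 to 0.018) for dDHX15, with a sign that turned past an adjusted p of 0.01 (0.0199), and -0.044 (-0.067 to -0.019) for dDHX38. The change differed beyond counting error, at a Benjamini-Hochberg adjusted p under 0.05, for 117 and 229 introns.

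Introns listed in both lines had the same direction in 58.0% (56.4 to 59.5) of cases in chromatin RNA and 72.2% (70.1 to 74.2) in total RNA, against 54.5% and 65.1% from the shares of risen introns in each line alone, so opposite moves were fewer than those shares give. An intron of MTR, methionine synthase (chromosome 1, 236808774 to 236810502), rose by 2.84 ± 0.19 (SE, log2) in dDHX15 chromatin RNA and fell by 1.39 ± 0.18 in dDHX38 chromatin RNA. An intron of SRRM2, a spliceosome protein (chromosome 16, 2759662 to 2759746), rose by 2.97 ± 0.15 and fell by 0.95 ± 0.13, and the others of the 10 with the largest sums lay in ATP8B2, TRMT1, FANCA, KDM5C, UTP14A, FAR1, BRWD1 and INTS3. In total RNA the RBM39 intron at 35732136 to 35734185 on chromosome 20 started from 0.510 and 0.523 in DMSO and went to 0.897 in dDHX15 and 0.279 in dDHX38, and DMTF1, GHDC, MUTYH, TMEM161B and MDC1 also rose in dDHX15 and fell in dDHX38. RPS6KA2, USP31 and POU2F1 went the other way, and RBM5 rose by 3.95 ± 0.17 and fell by 0.38 ± 0.13 (SE, log2). Of 3929 introns listed in chromatin RNA of both lines, 2108 fell in both, 1594 rose in dDHX15 and fell in dDHX38, 169 rose in both and 58 fell in dDHX15 and rose in dDHX38. Thus 90.4% (88.9 to 91.7) of the introns that rose in dDHX15 fell in dDHX38, against 97.3% (96.6 to 98.0) of those that fell in dDHX15 (Fisher's exact test, p = 1.8e-20). In total RNA 1872 introns were shared, and the shares were 77.6% (74.0 to 80.9) and 94.4% (93.0 to 95.6; Fisher's exact test, p = 7e-25). Over all comparisons 30380 introns were listed, of which 253 were listed in all 4, with 177 fallen and 2 risen in all 4.

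**Figure D3:**
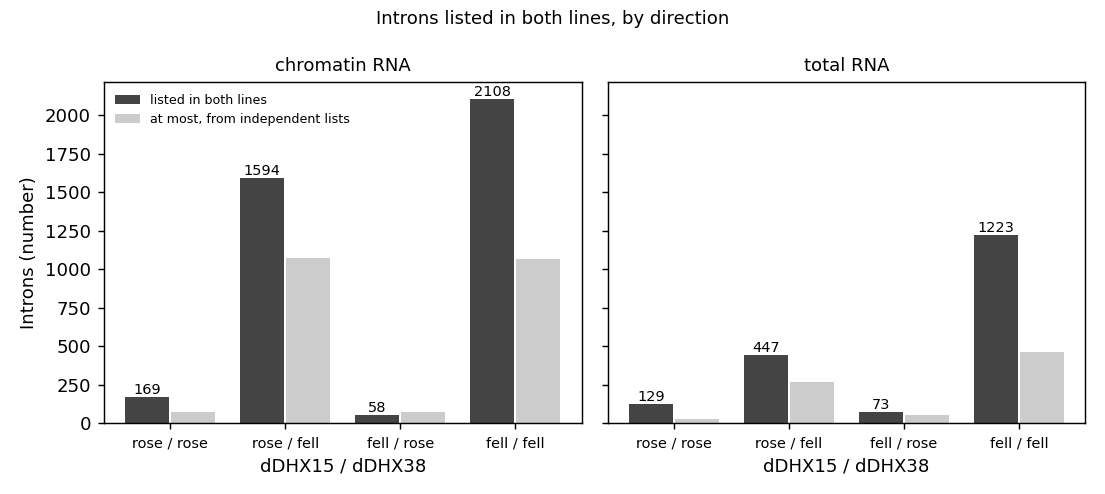
Number of introns listed in both lines (vertical axis) by direction in dDHX15 and dDHX38 (horizontal axis), for chromatin RNA (left) and total RNA (right). Dark bars are observed numbers, such as 1594 introns that rose in dDHX15 and fell in dDHX38 chromatin RNA. Light bars are the most that independent lists of these sizes would share if all tested introns were equally likely to be listed. Introns with many reads can be listed in both lines for that reason alone.

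The median length differed between risen and fallen introns in 3 of the 4 comparisons, in opposite ways for the lines. The median length was 714 bases for risen and 1431.5 bases for fallen introns in dDHX15 chromatin RNA, a difference of -717.5 bases (-1109 bases with 1 intron per gene), and in dDHX15 total RNA it was 628 and 1566 bases, a difference of -938 bases (permutation test, p = 1e-05 for both, adjusted p = 1.3e-05). In dDHX38 chromatin RNA risen introns were the longer, with 1529 against 930 bases (p = 1e-05, adjusted p = 1.3e-05), and 1e-05 is the smallest p these permutations can give. In dDHX38 total RNA the medians were 1006.5 and 896 bases (permutation test, p = 0.072, adjusted p = 0.072). The difference was 260 bases with 1 intron per gene (permutation test, p = 0.0081), but 40 bases with a mean of at least 20 reads (p = 0.55) and 38.5 bases past an adjusted p of 0.01 (p = 0.56). Among the authors' length classes, 55.9% (95% interval 54.0 to 57.7) of short introns (51 to 375 bases) rose in dDHX15 chromatin RNA. Medium introns were level with them at 56.6% (55.2 to 58.1), while 34.3% (31.6 to 37.1) of long and 17.5% (15.0 to 20.3) of extra long introns (8168 to 327713 bases) rose. In dDHX38 chromatin RNA 4.22% (3.64 to 4.85) of short and 15.8% (13.6 to 18.1) of extra long introns rose. In dDHX38 total RNA these shares were 9.87% (8.83 to 11.0) and 20.3% (17.1 to 23.7). There the odds ratio of rising, short or medium against long or extra long, was 0.618 (0.519 to 0.727), and 0.350 (0.243 to 0.507) within genes. Introns without GT-AG ends made up 0.660% of risen and 0.916% of fallen introns in dDHX15 chromatin RNA (Fisher's exact test, p = 0.17, adjusted p = 0.57), 1.07% and 1.08% in dDHX15 total RNA (adjusted p = 1), 0.524% and 0.928% in dDHX38 chromatin RNA (adjusted p = 0.57) and 0.992% and 1.27% in dDHX38 total RNA (adjusted p = 0.73).

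**Figure D4:**
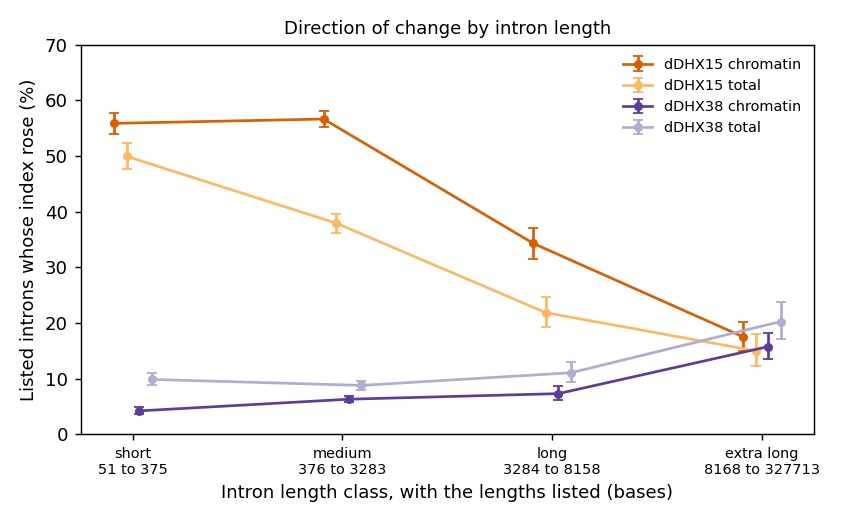
Share of listed introns whose splicing index rose (vertical axis, percent) by intron length class (horizontal axis, bases), for each line and RNA fraction. Points are shares and bars exact 95% binomial intervals. In dDHX15 chromatin RNA the share was 55.9% in short, 56.6% in medium, 34.3% in long and 17.5% in extra long introns.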

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

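The test of the compound alone and the ribosomal protein tests by length, baseline index and unspliced reads were chosen only after their results were seen, as was the comparison of snoRNA introns between fractions within deciles of the DMSO index; the carry-over test was prompted by the ribosomal protein counts, introns with a snoRNA were not part of the plan made before the data were examined, and the rule that leaves an interval holding both 1 and the unadjusted ratio open was set after the first results.

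The length trend differed between the lines: the odds that a short or medium intron rose, relative to a long or extra long one, were 6.77 times as high in dDHX15 as in dDHX38 for chromatin RNA (95% interval 5.65 to 8.10) and 5.00 times as high for total RNA (4.08 to 6.14). Both intervals treat introns of 1 gene as independent and would be too narrow where such introns move together. The odds ratio of 3.44 (3.08 to 3.89) in dDHX15 chromatin RNA was 2.77 (2.38 to 3.23) within deciles of the DMSO index, 3.37 (3.01 to 3.83) within deciles of read depth and 3.64 (3.02 to 4.40) within genes, which argues against each of these as the whole cause. The odds ratio in dDHX38 chromatin RNA, under the same compound, was 0.509 (0.435 to 0.598), so the compound did not go with the same trend in both lines. This cannot decide on an effect of dTAG13 itself, since loss of DHX38 could mask it there. No untagged line received dTAG13, so an effect of the compound in dDHX15 cells cannot be told apart from loss of DHX15. A candidate explanation is that loss of DHX15 acts on introns according to their length, a hypothesis found and tested on the same data. Differences between libraries or clones were not tested.

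Introns that hold a snoRNA gene rose in chromatin RNA more often than in total RNA: the ratio of odds ratios was 5.24 (2.19 to 12.5) in dDHX15 and 7.39 (2.42 to 22.6) in dDHX38. The intervals of these ratios treat introns of 1 gene, and fractions from the same plates, as independent, so they may be too narrow. Among them 75 rose and 19 fell in dDHX15 chromatin RNA, an odds ratio of 3.96 that was 3.36 (1.957 to 6.738) within deciles of length. It was 0.741 (0.275 to 1.75) within 24 host genes and 1.36 (0.721 to 3.25) within deciles of the DMSO index, so host genes that moved as a whole, or a low starting index, may account for the rise in chromatin RNA, although the DMSO index also enters the change itself. In dDHX38 chromatin RNA 26 rose and 70 fell, an odds ratio of 5.49 that was 6.14 (3.25 to 10.2) within deciles of length and 2.61 (1.35 to 4.62) within deciles of the DMSO index. Within 22 host genes it was 2.13 (0.822 to 5.67), and there an effect of the snoRNA and of the host gene cannot be told apart because few genes have introns of both kinds that moved apart. In total RNA 11 such introns rose and 25 fell in dDHX15, and 4 rose and 48 fell in dDHX38. The odds ratios there were 0.755 (0.253 to 1.68) and 0.742 (0.137 to 1.80), and both intervals include 1. Within deciles of the DMSO index they were 0.239 (0.0607 to 0.666) in dDHX15 and 0.229 (0.0397 to 0.532) in dDHX38. These intervals lay below those in chromatin RNA, by little in dDHX15. This argues against the starting index as the whole cause of the difference between fractions. Some introns with a snoRNA lie in ribosomal protein genes, such as the named introns of RPL10 and RPS12. Ribosomal protein genes had 202 risen and 3 fallen introns in dDHX15 chromatin RNA, but 7 and 7 in dDHX15 total RNA. The snoRNA comparison was not run without these genes, so the snoRNA and ribosomal protein patterns cannot be told apart here.

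Ribosomal protein introns rose more often than other introns in chromatin RNA of both lines, with odds ratios of 69.5 (30.3 to 232.2) in dDHX15 and 6.24 (3.85 to 9.55) in dDHX38. Within deciles of intron length they were 50.6 (20.6 to 179.4) and 8.04 (4.71 to 12.6), and within deciles of the DMSO index 34.4 (12.8 to 434.0) and 2.88 (1.74 to 4.51), which argues against length and starting index as the whole cause. If more mature mRNA had entered the chromatin fraction after dTAG13, other genes would rise in step with their spliced reads in total RNA. Outside the list, the odds ratio of rising for the third of such genes with the most spliced reads against the third with the fewest, within deciles of length, was 0.939 (0.786 to 1.13) in dDHX15 and 1.09 (0.847 to 1.40) in dDHX38, and both intervals include 1. Added mature mRNA alone would also leave unspliced reads unchanged relative to other introns. In dDHX15 the median log2 change of unspliced reads minus that of other introns was -0.55 (95% interval -0.67 to -0.43), and -0.58 (-0.70 to -0.45) against the mean of the medians of risen and fallen others. For spliced reads the difference was 0.26 (0.21 to 0.32). These values cannot decide on added mRNA alone, because the list holds mostly risen introns while the others rose and fell. All risen introns of dDHX15 chromatin RNA had a median unspliced fold of 0.675, dTAG13 over DMSO. The list's own median log2 change of unspliced reads was -0.55 (-0.66 to -0.42), a fall of similar size. In dDHX38 the differences in unspliced reads, -0.24 (-0.33 to -0.13) and 0.27 (0.19 to 0.38), disagree in sign because most other introns fell. There added mRNA alone cannot be told apart from an effect on these introns. Poly(A) RNA was removed from the chromatin RNA, which lowers mature mRNA by an amount not measured here. Carried-over mRNA together with fewer new transcripts of these genes cannot be told apart from an effect on these introns in either line, because the test by spliced reads covers only genes listed in total RNA and introns that were not listed are not analysed here.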

How the results depend on the processing

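The minimum index change of 0.1, the log2 minimum for the share that rose, and the settings for the difference between fractions and the read minimum for the overlaps were chosen after seeing the data. Each setting below that lowers a number of introns does so by construction, and for shares the cause was not tested. Past an adjusted p of 0.01, 6381 introns remained listed in dDHX15 chromatin RNA, the share that rose was 4.29% in dDHX38 chromatin RNA and 7.41% in dDHX38 total RNA, the lines shared 2256 introns in chromatin and 1168 in total RNA, and the median difference of absolute log2 changes between fractions of dDHX15 was 0.0199. With a mean of at least 20 reads, 5.92% and 9.19% rose in dDHX38 chromatin and total RNA. Counted as genes, there were 3172, 3504, 3883 and 4244 in dDHX15 chromatin, dDHX15 total, dDHX38 chromatin and dDHX38 total RNA, and with 1 intron per gene 52.8%, 38.3%, 8.70% and 13.5% rose. With a log2 change of at least 1, there were 6006 introns in dDHX15 chromatin and 8914 in dDHX38 chromatin RNA, and 49.0%, 34.4%, 4.49% and 8.51% rose. With an index change of at least 0.1, there were 3259 introns in dDHX15 total and 4421 in dDHX38 total RNA, and 41.8%, 5.54% and 11.1% rose in dDHX15 total, dDHX38 chromatin and dDHX38 total RNA. In dDHX38 total RNA the length difference was 260 bases with 1 intron per gene (permutation test, p = 0.0081), 40 bases with a mean of at least 20 reads (p = 0.55) and 38.5 bases past an adjusted p of 0.01 (p = 0.56). With 1 intron per gene the difference in introns without GT-AG ends in dDHX15 total RNA turned to 0.0910 percentage points (Fisher's exact test, p = 0.86), without a call in either setting; the cause was not tested. Risen and fallen introns of dDHX15 chromatin RNA were so near equal in number that their order turned with the setting. Another 53 values for these comparisons kept their direction and side of the threshold, or stayed within the limits set for counts and shares. Some of them still moved by over 1.5 times: the difference between fractions was -0.0245 in dDHX15 with the read minimum and -0.0270 in dDHX38 past an adjusted p of 0.01, the length difference in dDHX15 chromatin RNA was -1109 bases with 1 intron per gene, and such differences in introns without GT-AG ends, none of them called, lay between -0.391 and -0.0621 percentage points. Over the read minimum and the stricter adjusted p the calls of gene lists were kept 21 times and lost 3 times, and 1 was gained with the read minimum, SR proteins with risen introns in dDHX38 chromatin RNA. No paired analysis was possible because the pooled columns carry no library numbers. For the same reason the replicate block, DESeq2, another scaling, a pseudocount and leaving out libraries were not run, and annotated introns alone would change nothing since all are annotated. Changes of 0.5 on the log2 scale were mostly not called in the simulated counts, where few introns were changed. How many such changes were missed in the deposited tables was not measured.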

Other observations

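The gene-wide test described here was written before its result was seen, and the genes named in the next paragraph, the split by position and the count of AT-AC introns were chosen after their values were seen.

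Several genes with many listed introns had all of them in 1 direction, and their introns that were not listed are not analysed here. Over all introns 50.2% rose in dDHX15 chromatin RNA and 36.8% in dDHX15 total RNA. In dDHX15 chromatin RNA SLIT2, an axon guidance ligand, had 20 risen and 0 fallen introns with a median log2 change of 1.35, and HEATR1, a ribosome biogenesis factor, had 16 risen and 0 fallen. TRIO, a guanine nucleotide exchange factor, had 0 risen and 17 fallen introns, with a median of -1.35. In dDHX15 total RNA the chromatin remodeller CHD1 had 0 risen and 10 fallen introns. In the dDHX38 comparisons most introns fell, so such genes are not named.

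The share of risen introns differed with position in the gene, without a common trend. Position was the distance of an intron from the 5 prime end of its gene, over the gene length less the intron length. This scale, which differs between introns of 1 gene, was cut into 5 equal parts. In dDHX15 chromatin RNA 43.8% (95% interval 41.6 to 46.0) of introns in part 1, at the 5 prime end, and 57.8% (55.5 to 60.0) of those in part 5 rose. In dDHX15 total RNA these shares were 39.2% (36.4 to 42.0) and 33.3% (31.2 to 35.3), with the highest share, 43.2%, in part 2. They were 6.57% and 11.5% in dDHX38 chromatin RNA, and 14.1% and 11.8% in dDHX38 total RNA, where part 3 had the lowest share, 7.20%. Whether other properties of the introns explain these shares was not tested. Introns with AT-AC ends, a mark of the minor spliceosome, were few, with 1 risen and 5 fallen in dDHX15 chromatin RNA, 1 and 11 in dDHX15 total RNA, 0 and 14 in dDHX38 chromatin RNA and 3 and 20 in dDHX38 total RNA.

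One hypothesis was that introns of a gene share a direction only because they share length and starting index. In dDHX15 chromatin RNA 56.4% of 1946 genes with at least 2 listed introns had both risen and fallen introns. Shuffling directions among introns of similar length and DMSO index gave 65.2% to 70.7% over 1000 shuffles, so fewer genes were mixed than these properties alone would give. What else the introns of a gene have in common, and whether it could act on splicing, was not tested.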
